A study of Homo sapiens with 2 samples.

How the data were processed

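Primary human keratinocytes, the main cell type of the epidermis, were grown in serum-free medium to passage 3, and their chromatin was crosslinked with 1% formaldehyde for 8 min and sonicated, per the labels' protocols. The first library was made from chromatin immunoprecipitated with an antibody against JunB, a subunit of the AP-1 transcription factor, and the other from input DNA that was not immunoprecipitated. Each library was made from 10 ng of DNA. No value below has a replicate, so no test between conditions was possible. Every p-value of the authors describes these libraries and not the condition.

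The data are 1 deposited list of genomic regions assigned to RefSeq promoters. BWA and the genome build hg19 are named in the submitters' processing notes. The peak caller, the read filters, the width taken as a promoter, the number of reads per library and the way regions were picked for the list are not given in the sources used here. Each region carries a chromosome, a start and an end, which are printed as deposited. The deposited width equals the end minus the start in all 404 regions, and whether positions count from 0 or from 1 is not given. The list has no distances to start sites, and no genome of that build was used here, so the position of a region relative to an exon, intron or start site is not reported.

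The authors gave 4 values per region, named in the file header. The first is the log10 of the region's p-value, which the authors' unnamed caller computed and the authors deposited as a negative number. The second is the linear ratio of ChIP to control. The third is the maximum peak height, a deposited signal in whole numbers of overlapping reads or fragments. Which of these was counted is not given in the sources used here. The fourth is the region's width in base pairs. The header does not name the base of the logarithm, so it was worked out from the values. On 20 autosomes some regions had a whole-number ratio of 5 or 6, and on 14 of these at least 3 further regions had a ratio within the next unit and a height 1 above it. There the log p fell with the ratio, with a median step of 1.31 to 1.43 per unit of ratio. A Poisson tail with 1 mean per chromosome, fitted to the level at the whole number alone, gave this step to within 0.00138 in base 10, and missed it by at least 0.330 on every such autosome if the logarithm was natural. The fitted background means ran from 0.224 to 0.378 overlapping reads or fragments. With these means each log p converts to an equivalent ChIP height, and that height divided by the deposited ratio gives the control value behind the ratio. Of 390 autosomal regions 80 served to fit the means and have a control value of 1 by construction. In the other 310 the control value was within 0.01 of 1 in 184 (59.4%), was below 1 by more than that in 0, and was at most 1.23. Read in this way, the ratio is close to a ChIP height over a control held at 1 or slightly above. This reading was derived from the values, since the caller is not named.

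Depth limits all values. The maximum heights ran from 4 to 20. An exact Poisson 95% interval on a height of 7, the median, is 2.81 to 14.4, and on a height of 20 it is 12.2 to 30.9. These intervals cover counting error only and take no account of the selection of regions for their height, and whether duplicate reads had been removed is not given in the sources used here.

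Genes were taken from the RefSeq transcript accessions of each region, looked up in a table of human RefSeq genes on GRCh38.p14, which was used for names, transcript numbers, gene order and the number of genes per chromosome but not for coordinates. Of 656 accessions 638 matched, and every region received at least 1 gene. Regions whose accessions named several genes kept all of them. Symbols are printed as in the list, with the present symbol added where it differs. In 1 region the symbol had been turned into a date by a spreadsheet, and its accession names MARCHF6.

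17 gene lists with 640 entries were fixed before the data were examined, of which 6 entries matched no gene. Each list was compared with the 29989 genes that have a curated RefSeq transcript by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 17 lists and a threshold of 0.05. The gene table is on a later build than the list, so this background may hold genes that could not be listed. The regions per autosome were compared with the share of genes by two-sided exact binomial tests, adjusted over the autosomes. The design names the share of genes and the list of alternatives names start sites as the starting point, so the share of genes was taken as the main expectation after both results were known, and both are given. Start sites were counted as annotated transcripts. Regions on the sex chromosomes count in the totals and were not compared. Relations between the scores were tested across regions with 100000 permutations. Regions and genes are not independent replicates. The gene list test was tested on simulated data, with 423 genes drawn from the real background in 200 simulations per setting. With 6 genes of the basal keratinocyte list planted, that list was called in 100% of simulations, and with 3 planted in 0.5%. The planted settings fix the number of list genes with a region, and 6 is also the observed number. The rates therefore follow largely from that number and do not measure power. In simulations with no planted gene, a list other than that one was called in 2.5%. Computation used Python 3.11.15, scipy 1.17.1 and pandas 2.3.3.

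The genes named below are the 20 with the highest ratio, the column taken as the ranking score before the data were examined, and up to 6 per fixed list. A further part of the rule, the genes with regions closest to and farthest from a start site, needs distances and was not applied. A few genes that this rule names are not reported here. Genes chosen after their values were seen are marked as such. Alternatives covered the counting unit, merging of neighbouring regions, the 202 regions with a ratio at or above the median, the background genes, the gene assigned to a region, gene clusters, the expected share per chromosome and the correlation measure. The planned tests of distance to a start site and of AP-1 and CRE sequence sites were not run, since both need start sites or a genome of the files' build.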

Results

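JunB occupancy was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in primary human keratinocytes. The data compare 1 JunB library with 1 input library, and the question the design addresses is at which promoters JunB-bound DNA was recovered above the control. Neither library had a replicate. The list holds 404 separate promoter regions on hg19, which carry 387 gene symbols and, through their transcript accessions, 424 genes. All ratios, heights and log10 p-values of regions are the authors' own. In 38 regions the accessions named 2 or more genes, and 28 regions were assigned to non-coding transcripts only. The median ratio of ChIP to control was 5.77, with an interquartile range of 5.18 to 6.40 and a maximum of 12.1. The median maximum height was 7 overlapping reads or fragments, and 270 regions (66.8%) had a height of 7 or less. The median width was 141 bp, between 99 and 1097 bp. No region had a log10 p above -5, and the weakest listed value was -5.12. The Poisson reading of these values holds no adjustment for the number of places searched. A log10 p near -5 therefore does not by itself exclude a region found by chance.

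Among the regions with the highest ratios, a ratio of 11.8 was found at LOC100130581, now LINC00910, a non-coding RNA gene (chromosome 17, 41466016 to 41466234, height 17). S100A2, a calcium-binding protein gene expressed in basal keratinocytes, had a ratio of 10.4 and a height of 17 (chromosome 1, 153538973 to 153539376). A second region of S100A2 (153538300 to 153538469) had a ratio of 6.58. RPPH1, the RNA component of RNase P, had a ratio of 9.72 in a region that its accessions share with PARP2 (chromosome 14, 20811523 to 20811875). PPP1R14B had a ratio of 9.66, TNFRSF12A, the receptor of the cytokine TWEAK, had 9.56, and CRABP2, a cellular retinoic acid binding protein, had 9.26.

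The rest of the 20 highest ratios ran from 8.94 down to 8.02. They were at RANGAP1, LOC283104 (whose accessions name the non-coding genes SBF2-AS1 and LINC02709), DHRS13, FAM83A, BCL9L, DAPP1, MAP2K3, CNTN1, STK40, EEF1A1, TM9SF3, ALOXE3 and GRHL3. EEF1A1, the translation elongation factor, had 2 regions with ratios of 8.16 and 6.37. ALOXE3, a lipoxygenase of the epidermal barrier, had a ratio of 8.12 (chromosome 17, 8021690 to 8021908), and GRHL3, a transcription factor of epidermal differentiation, had 8.02 (chromosome 1, 24643791 to 24643959). Counting error alone limits this order. A height of 12, as at EEF1A1, has an exact Poisson 95% interval of 6.20 to 21.0, which includes the height of 17 at LOC100130581 and S100A2.

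**Figure D1:**
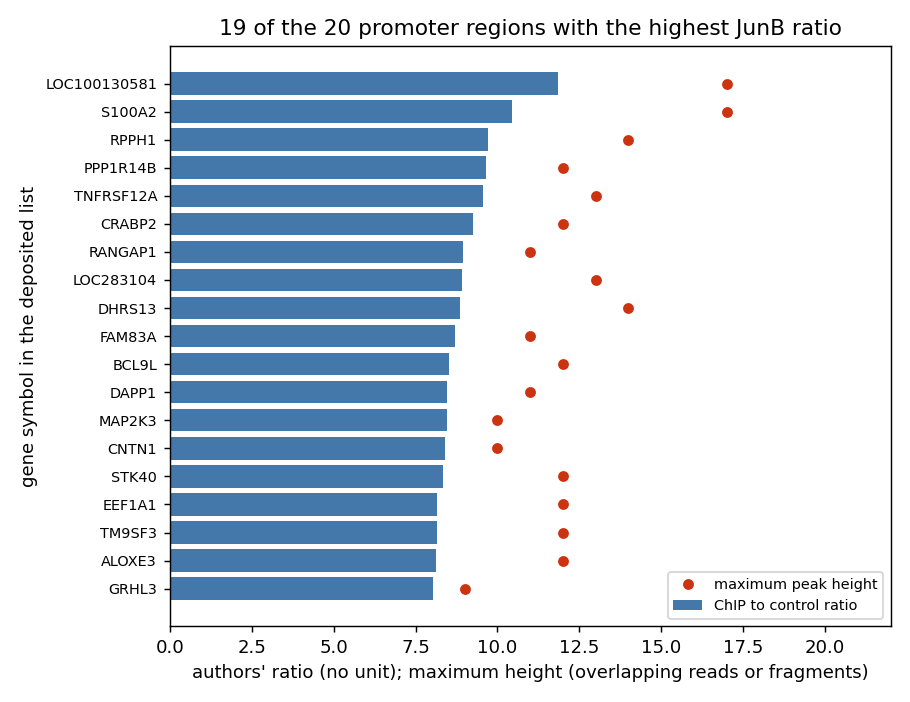
Ratio of ChIP to control (bars) and maximum peak height in overlapping reads or fragments (points) for 19 of the 20 regions with the highest ratio, by gene symbol, from 1 JunB and 1 input library. Ratios run from 11.8 at LOC100130581 to 8.02 at GRHL3, and heights from 17 at LOC100130581 and S100A2 to 9 at GRHL3.

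Genes of the basal keratinocyte layer and its attachment to the basement membrane were over-represented. Of 27 genes in this list 6 had a region (22.2%, exact 95% interval 8.62 to 42.3%), against 1.41% of all background genes. The odds ratio was 20.2 (two-sided Fisher's exact test, p = 1.75e-06, adjusted p = 2.98e-05). Against protein-coding genes only it was 14.3 (Fisher's exact test, adjusted p = 0.000208). PLEC, which encodes the hemidesmosome linker plectin, had 2 regions on chromosome 8 with ratios of 6.94 (145014277 to 145014729) and 5 (145013835 to 145013979). LAMA3, a laminin chain of the basement membrane, had a ratio of 5.32 (chromosome 18, 21452640 to 21452936). COL7A1, the collagen of anchoring fibrils, had a ratio of 6.35 (chromosome 3, 48632991 to 48633600). KRT5, the basal layer keratin, had a ratio of 6 (chromosome 12, 52914181 to 52914308), and the integrin gene ITGA2 had 5.34 (chromosome 5, 52283571 to 52283695). Heights in these regions ran from 5 to 9, both at PLEC. The ratios of 6 at KRT5 and 5 at PLEC were the lowest whole-number ratios listed on their chromosomes. 

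The fixed list of EGF receptor ligands and MAP kinase feedback genes is called the EGF receptor and MAP kinase list below. It does not cover all genes of this signalling. Of its 43 genes 4 had a region (9.30%, exact 95% interval 2.59 to 22.1%). The odds ratio was 7.23 (Fisher's exact test, p = 0.00312, adjusted p = 0.0265). MAP2K3, a MAP kinase kinase, had ratios of 8.45 (chromosome 17, 21191419 to 21191588) and 7.03 (21189674 to 21189841). ERBB3, a receptor of the EGF receptor family, had a ratio of 5.80, DUSP1, a MAP kinase phosphatase, had 5.73, and HBEGF, a ligand of the EGF receptor, had 5.69. This call was lost with protein-coding genes as the background (Fisher's exact test, adjusted p = 0.0872) and under 4 other alternatives, with adjusted p-values from 0.0191 to 0.478 over the 6 alternatives that count single genes.

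The AP-1 family and its relatives had a region at 3 of 34 genes (8.82%, exact 95% interval 1.86 to 23.7%), which did not pass the adjustment (odds ratio 6.81, Fisher's exact test, p = 0.0121, adjusted p = 0.0683). JUN had 2 regions on chromosome 1, with ratios of 7.41 (59248351 to 59248515) and 6.90 (59248062 to 59248186). FOSL1 had a ratio of 6.10 (chromosome 11, 65666686 to 65667059). JUNB itself had a ratio of 5.80 and a height of 7 (chromosome 19, 12902166 to 12902283). In the 202 regions with a ratio at or above the median, 3 of the 34 genes gave an adjusted p of 0.0157 (Fisher's exact test), and over the 6 alternatives that count single genes the adjusted p ran from 0.0157 to 0.167.

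The other epidermal lists did not pass against all background genes. In the list of 71 differentiation and cornified envelope genes only ALOXE3 and GRHL3 had a region (2.82%, exact 95% interval 0.343 to 9.81%; p = 0.265, adjusted p = 0.500, Fisher's exact test). Among 18 S100 genes S100A2 and S100A10 had one (odds ratio 8.77, p = 0.0262, adjusted p = 0.111, Fisher's exact test), with a ratio of 4.96 at S100A10. None of the 5 stress and wound keratins had a region, which leaves an exact 95% interval for their share of up to 52.2%.

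**Figure D2:**
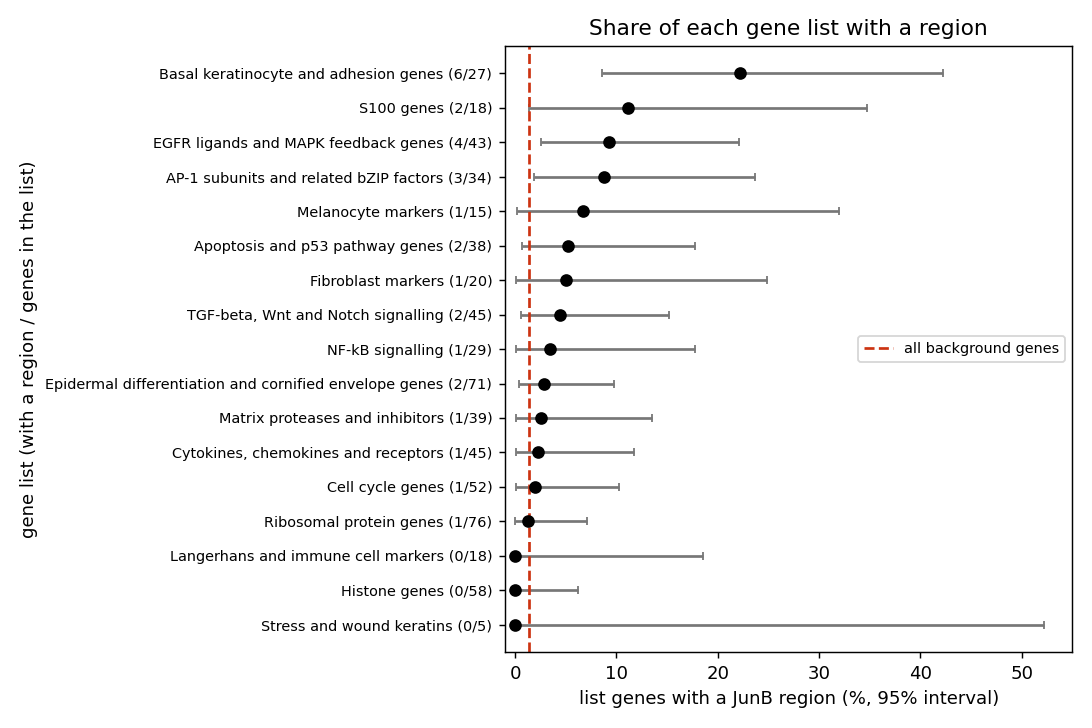
Share of the genes in each of 17 lists fixed beforehand that had a JunB promoter region (points, in percent) with exact 95% binomial intervals; the dashed line marks 1.41% of all background genes. The basal keratinocyte list, at 22.2%, is the highest, and ribosomal protein genes, at 1.32%, lie next to the line.

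The remaining signalling and growth lists had 1 or 2 genes with a region each, and none passed (Fisher's exact test, p from 0.100 to 0.523, adjusted p from 0.341 to 0.683). FADD, an adaptor of death receptors, had a ratio of 7.59, and the decoy receptor gene TNFRSF10C had 5.24, together 2 of 38 apoptosis and p53 pathway genes. The Notch target HES1 had a ratio of 5.79 and the Notch effector RBPJ 5, together 2 of 45 genes of TGF-beta, Wnt and Notch signalling. CDKN1A, which encodes the cell cycle inhibitor p21, was the 1 gene of 52 in the cell cycle list and had 2 regions on chromosome 6, with ratios of 7.11 (36647990 to 36648247) and 5.39 (36648407 to 36648510). NFKBIA, the inhibitor of NF-kB, had a ratio of 6 (1 of 29 genes), and IL1B, the cytokine interleukin-1 beta, had 5.18 (1 of 45). Of the matrix proteases and inhibitors 1 of 39 genes had a region. The ratios at RBPJ and NFKBIA were the lowest whole-number ratios listed on their chromosomes.

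Lists of other cell types and of general genes did not pass the test either. KIT was the 1 of 15 melanocyte markers with a region, at a ratio of 5, and VIM, the intermediate filament gene vimentin, the 1 of 20 fibroblast markers, at 7.51 (Fisher's exact test, p = 0.192 and 0.247, adjusted p = 0.466 and 0.500). The ratio at KIT was the lowest whole-number ratio listed on its chromosome. None of 18 Langerhans and immune cell markers and none of 58 histone genes had a region, which leaves exact 95% intervals of up to 18.5% and 6.16%. Among 76 ribosomal protein genes RPS15 alone had one, at a ratio of 5.21 (1.32%, exact 95% interval 0.0333 to 7.11%). For the ribosomal protein, histone, immune cell and stress keratin lists both the Fisher's exact p and the adjusted p were 1.

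16 gene symbols had more than 1 region. ANKRD30BL had 3 within 2623 bp, with ratios of 4.98 to 5.80. The control values recovered for these regions ran from 1.11 to 1.23, and 1.23 was the highest of 390 regions. A further 15 genes had 2 regions. Besides JUN, PLEC, CDKN1A, S100A2, MAP2K3 and EEF1A1 these were BCL9L, C4orf42 (now CTBP1-DT), EMP3, MALT1, NEU2, NFIB, PDE4DIP, REPIN1 and TGIF1. Among the genes from BCL9L to TGIF1, each taken at its region with the higher ratio, the highest were BCL9L, MALT1 and EMP3. Ratios there were 8.51 at BCL9L, a coactivator of beta-catenin, 7.56 at MALT1, a protease of NF-kB signalling, and 7.37 at EMP3.

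The authors' list carries written remarks beside 8 regions, named here after their values were seen. The remark that the region was absent from c-Jun stands beside KRT5, NFKBIA, MIR135B, TFAP2A, PIM1, COL12A1 and CAV1, and a remark that it was absent from A431, an epidermoid carcinoma cell line, stands beside 1 of the 2 MAP2K3 regions. Their ratios ran from 5 at COL12A1 to 7.03 at MAP2K3, with a median of 5.65 against 5.77 over all regions. The ratio at COL12A1 was also the lowest whole-number ratio listed on its chromosome. TFAP2A, a transcription factor of the epidermis, had a ratio of 5.84 and the kinase gene PIM1 had 5.34. The data these remarks refer to, and whether other regions were looked up in the same way, are not given in the sources used here, and no comparison with c-Jun was made.

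The regions were spread over all 22 autosomes, 395 in all. Tested against the share of genes, 0 autosomes passed the adjustment and 9 had an unadjusted p under 0.05 (two-sided exact binomial tests). Chromosome 6, which holds CDKN1A, EEF1A1, PIM1 and TFAP2A, had 36 regions where 21.4 would be expected (exact p = 0.00253, adjusted p = 0.0556). Against the share of annotated transcripts it was the 1 autosome that passed (exact binomial test, adjusted p = 0.0275). Chromosome 2, which holds IL1B, had 41 regions where 26.8 would be expected (exact p = 0.00674, adjusted p = 0.0657), and chromosome 20, which holds FERMT1, had 3 where 11.2 would be expected (exact p = 0.00896, adjusted p = 0.0657). On 10 autosomes (2 to 9, 13 and 18) regions were listed at a ratio of exactly 5, and these held 248 of 395 regions (62.8%, exact 95% interval 57.8 to 67.6%) against 43.8% of genes. The 10 were grouped after the values were seen. Among regions with a ratio of 6 or more they held 51 of 167 (30.5%, exact 95% interval 23.7 to 38.1%).

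**Figure D3:**
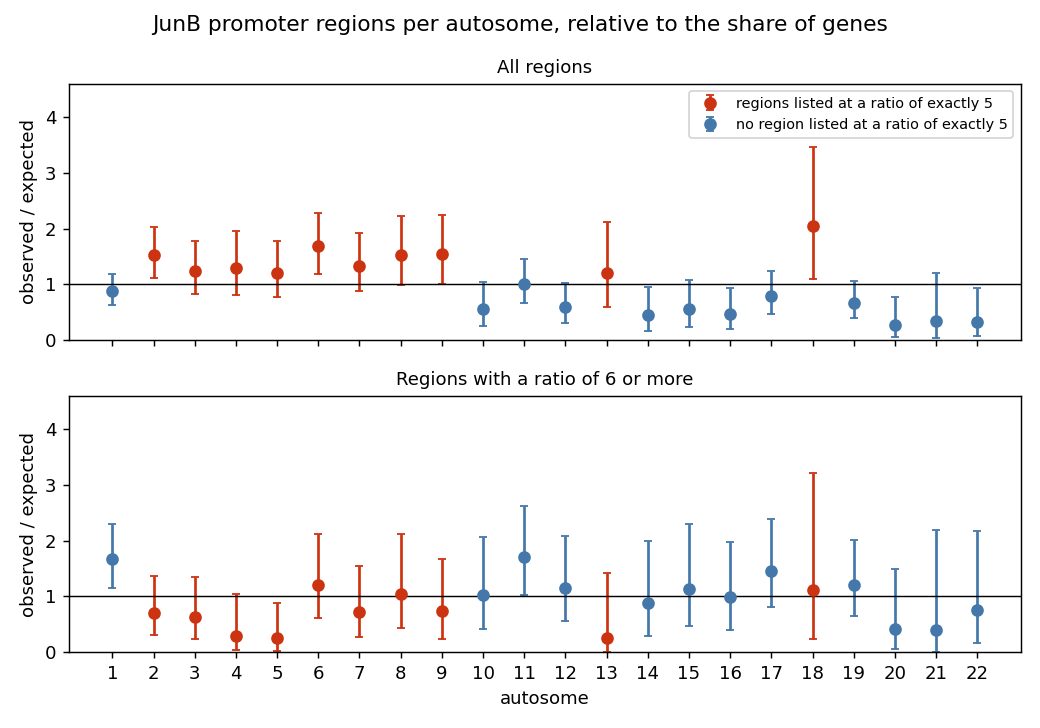
Observed over expected number of JunB promoter regions per autosome, with the expectation from the share of genes and exact 95% binomial intervals as bars, for all regions (top) and for those with a ratio of 6 or more (bottom); red marks autosomes with regions listed at a ratio of exactly 5. Red autosomes hold 62.8% of all regions and 30.5% of those with a ratio of 6 or more.

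The scores of a region moved together across the 404 regions. Higher ratios went with a lower log10 p (Pearson's r = -0.94, Spearman's rho = -0.89) and with greater height (r = 0.89, rho = 0.83), and less closely with width (r = 0.54, rho = 0.52). Log10 p and height gave r = -0.94 and rho = -0.89. The relation of ratio to log10 p follows from how these scores are built, since the log10 p is close to a Poisson tail of an equivalent ChIP height and the ratio close to that height over a control near 1. The maximum height is a separate value, but the equivalent height exceeded it in 0 of 390 regions, so its relations are not independent of that construction, and no p is given for these 3. The relation of ratio to width had a permutation p of 1e-05 for r and for rho, the smallest that 100000 permutations can give, before and after adjustment over the 4 relations computed. Width and ratio were both called from the same reads, and how the caller set the width is not given. The p is therefore not evidence of a relation beyond the calling of regions. Regions are not independent replicates. Without the 2 regions farthest from the median r was -0.93 for ratio and log10 p, 0.87 for ratio and height, 0.49 for ratio and width and -0.92 for log10 p and height.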

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

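Which alternatives to try was fixed before the data were examined, except the restriction to a ratio of 6 or more and the removal of regions exactly 169 bp wide, which were chosen after the list was seen. The 404 regions stayed 404 with overlapping regions merged and became 393 with regions within 1000 bp merged; those with a ratio at or above the median are 202 regions and 215 of the 424 genes, by construction. Of 17 gene lists 2 were called. This became 1 with a protein-coding background, 1 with genes that have coding transcripts, 1 at a ratio of 6 or more and 1 without the 169 bp regions, each time with the EGF receptor and MAP kinase list lost (Fisher's exact test, adjusted p = 0.0872, 0.0869, 0.478 and 0.0979). It became 4 with neighbouring list members counted once (the S100 and AP-1 lists were added), but this setting joins genes of the list and not of the background, so it raises the odds ratio of clustered lists by construction and the added calls are not read as enrichment. With the 202 regions it stayed at 2, with the AP-1 list in place of the EGF receptor and MAP kinase list (Fisher's exact test, adjusted p = 0.216). The smaller backgrounds raise the expected number of genes per list; the cause of the other changes was not tested. The basal keratinocyte list passed in each of the 6 settings that count single genes, with odds ratios from 14.3 to 29.9 and adjusted p-values from 1.75e-05 to 0.000673. The number of autosomes past the threshold was 0 against the share of genes, 1 (chromosome 6) against the share of annotated transcripts and 0 at a ratio of 6 or more; at an unadjusted p under 0.05 it was 9, 7 and 3. The correlation of ratio and width kept its sign under both alternatives. No paired analysis was possible because each group has 1 library, and leaving out a replicate was not possible for the same reason. The planned tests of distance to start sites and of AP-1 and CRE sites were not run. At maximum heights of 4 to 20, a gene without a listed region is not shown to be unbound.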

Other observations

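The tests of caveola and calpain genes and the comparisons with ribosomal protein genes were chosen after their results were seen, and the test at a ratio of 6 or more was added once the excess on some autosomes had been seen, though before its own outcome was. Regions also lay at 3 of 7 genes of caveolae, the flask-shaped pits of the plasma membrane. The ratios were 7.92 at PTRF (now CAVIN1), 7.41 at PRKCDBP (now CAVIN3) and 5.28 at CAV1, which encodes their main coat protein (Fisher's exact p = 0.000256 against protein-coding genes). Of 17 genes of the calpain system, the calcium-dependent cysteine proteases, 4 had a region. CAPN2 had a ratio of 7.24, CAPN1 5.45, the shared small subunit CAPNS1 6, and CAST, the inhibitor of these proteases, 5 (Fisher's exact p = 0.000297). The ratios at CAPNS1 and CAST were the lowest whole-number ratios listed on their chromosomes. Both groups were picked because their genes stood in the list, so these p-values cannot decide whether either is over-represented. A scan of 657 families with a shared symbol root, each of 5 or more genes, found 0 over-represented after Benjamini-Hochberg adjustment in two-sided Fisher's exact tests. At an unadjusted p under 0.05 there were 8 families with more genes than expected and 1, the ZNF genes, with fewer. The scan does not decide on caveola or calpain genes, since it joins genes by symbol root only. CAV1 and the CAVIN genes have different roots, and its CAPN family (2 of 14 genes with a region) leaves out CAPNS1 and CAST.

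Single genes of interest to skin biology, also chosen after their values were seen, include FERMT1, the kindlin of epidermal adhesion, with a ratio of 7.91, the retinoic acid receptor gene RARG with 6.98, the desmosome genes PKP3 with 6.90 and PKP2 with 6.44, and CALML3 with 6.62. KEAP1 and SQSTM1, both of the oxidative stress response, had 7.20 and 6.24, and the hepatocyte growth factor receptor gene MET had 6.72.

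The excess of regions on 10 autosomes may come from the calling limit and not from where JunB binds. The fitted background mean was lower there (0.257 overlapping reads or fragments or less) than on the 10 others for which it could be fitted (0.290 or more), so that a height of 5 gave a p under 1e-05 on the former while 6 were needed on the latter. The 10 autosomes held 62.8% of all regions against 43.8% of genes. At a ratio of 6 or more their share was 30.5% (exact 95% interval 23.7 to 38.1%), so the excess was gone and the share lay below that of genes. Leaving out ratios under 6 lowers this share by construction, and a given height is easier to reach by chance where the background is higher. Both lower the share, so its fall does not decide between the calling limit and where JunB binds. The values show only that the excess lay among ratios under 6, and no biological explanation was tested.

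The excess of basal keratinocyte genes is harder to place. Strongly transcribed, open promoters can yield ChIP signal with any antibody. Of 76 ribosomal protein genes, which every cell transcribes strongly, 1 had a region (upper 95% bound 7.11%). The lower 95% bound for the basal list was 8.62%. These intervals overlapped under 3 of the 6 alternatives that count single genes (6.30% against 7.11% without the regions 169 bp wide, and 4.19% against 4.74% both in the 202 regions and at a ratio of 6 or more). The lists differed in Fisher's exact tests with p from 0.00118 to 0.00450 over these settings. This comparison was chosen after both shares had been seen and rests on 1 class of genes, so it does not decide whether transcription contributes. The basal genes have more annotated transcripts than most (median 3 against 1). Of 10000 random lists matched on the number of transcripts, 0 held as many genes with a region (at most 5, on average 0.45). Transcripts were counted on GRCh38.p14 and not on the build of the list, so the promoters searched per gene may not have been matched. Effects of transcription and of chromatin that is open in keratinocytes in particular stay open, since no control antibody or JunB-depleted sample was analysed here. Binding of JunB to these promoters is a hypothesis on the same footing.

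A width of exactly 169 bp was shared by 33 regions (8.17%), while the next commonest width, 102 bp, was shared by 10. Of the control values recovered for 390 regions, the highest, 1.23, belonged to a region of ANKRD30BL.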
